A study of Mus musculus with 30 samples.

How the data were processed

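RNA from the colon of 30 mice of 6 genotypes, 5 mice each, was made into 3′ tag libraries with the Lexogen QuantSeq forward kit, per the labels' protocols, from 2 µg of total RNA of each mouse with an RNA integrity number above 7. The values deposited by the authors are estimated counts of reads per Ensembl gene, which need not be whole. Per the submitters' processing notes, cutadapt 3.2, Subread, featureCounts 2.01 and R 4.0.0 were used with genome build GRCm38 (mm10). Aligner settings, the strand setting, the annotation release and the way a read was divided between genes are not given in the sources used here; without a stated strand setting, an antisense gene and its partner cannot be told apart. Of the non-zero values 11.2% were not whole numbers. Library totals of 3516792.6 to 5823059.7 reads make 1 read worth about 0.232 CPM (reads of a gene scaled to a common library total) in the median library, so genes at a few CPM rest on few reads. A 3′ tag protocol reads the end of a transcript, gives no isoform and needs no correction for gene length. No molecular identifiers are named in the sources used here, so reads can hold PCR copies.

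The table had 55579 features, of which 92 were spike-in sequences with 0 reads and were left out. Of the 55487 gene identifiers 55141 were matched to a symbol in the gene annotation of the same build, and the 346 others held 0.0190% of the reads. Estimated counts were rounded to whole numbers, which changed a library's total by at most 0.00321%. Genes were kept by filterByExpr of edgeR over the groups, which left 15458 (27.9% of the genes). All libraries entered 1 fit with a coefficient per group (R 4.3.3, edgeR 4.0.16, TMM normalization, quasi-likelihood F test), and p was adjusted by Benjamini-Hochberg within each of the 11 comparisons, with a threshold of 0.05. Each gene had 1 dispersion shared by all groups, although the spread between replicates differed between groups. The common biological coefficient of variation was 0.186. The SE of a log2 fold change is its size divided by the square root of F. CPM are given as mean ± SD over 5 mice, and principal components were taken of the 1000 most variable genes on the log2 CPM scale with a prior count of 2.

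The comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. The rule named the targeted genes, the 8 genes of smallest p in each direction with an absolute log2 fold change of at least 1 (without immunoglobulin and T cell receptor segments and genes known by a model or clone number), and up to 4 members of smallest p of each list. The 34 lists, written from textbook knowledge, were XBP1 target secretory genes, ER stress sensors and chaperones, ATF4 integrated stress response, goblet cell, absorptive colonocyte, epithelial antimicrobial, inflammatory cytokines and NF-kB targets, type I interferon response, interferon gamma response and antigen presentation, cell death machinery other than the targeted genes, stem cell and WNT targets, proliferation, epithelial regeneration, tissue remodelling, fatty acid oxidation and ketogenesis, cholesterol synthesis, xenobiotic metabolism, enteroendocrine, tuft cell, neutrophil, monocyte and macrophage, T and NK cell, B cell, plasma cell, eosinophil and mast cell, smooth muscle, fibroblast, endothelium, enteric neuron and glia, adipose, small intestine and Paneth cell, squamous epithelium, immediate early genes and mitochondrially encoded. Of these 33 had at least 3 measured members and were tested in each comparison (363 tests, adjusted together) with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Whole colon RNA mixes many cell types, and a list is no measure of a cell number.

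Overlaps of calls between comparisons that share libraries were set beside simulated unchanged groups, the overlap of independent lists, and splits of the shared libraries in 3 and 2. Comparisons against groups of the same sizes drawn by regrouping the libraries, 100 for each comparison, are given with the closing observations. Alternatives were DESeq2 size factors, no low-count filter, a stricter one, a fit of only the groups compared, limma voom with quality weights, DESeq2 1.42.0, the replicate number as a block, the sex of the animal as a term, and each library of the compared groups left out in turn. Chosen after seeing the data were fits in males only and females only, fits without genes within 20 Mb of the targeted loci, some settings for the overlaps, and leaving out libraries for the overlaps and lists. Sex was called from Xist and Y-linked genes. Replicates are separate mice, per the labels' protocols. The spread between each pair of replicates was at least 3.25 times that of Poisson counts within each group, so no library was counted again within its group. Pairs of libraries from different groups were not compared in this way.

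The procedure was tested on simulated data made for the double knockout against WT, with 15247 genes of which 200 were changed. It called 160 genes, 2 of them falsely, and found 34% of the genes changed by a log2 fold change of 0.5, 82% at 1, 100% at 2 and 100% at 3. The changed genes were drawn from those above a minimum mean level, and all groups were simulated with the same dispersion. Recovery of low genes and of changes in a more variable double knockout was therefore not measured. Scaling by DESeq2 size factors moved the median log2 fold change of all genes by at most 0.00489 in each comparison.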

Results

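Gene expression was measured by 3′ tag sequencing, which reads transcripts near their 3′ end, in total RNA from the colon of 30 mice, 1 library per mouse. The 6 genotypes held 5 mice each. They were WT controls, the Xbp1 knockout, the Casp8 knockout, the double knockout of both genes, and triple knockouts that lacked TNFR1 or MLKL in addition, here called the TNFR1 and the MLKL triple knockout. The genotype labels place the Xbp1, Casp8 and Tnfr1 deletions in intestinal epithelial cells (IEC), which line the gut, and name no cell type for Mlkl. The RNA came from colon tissue, with its muscle, immune and nerve cells. XBP1 is a transcription factor that expands the secretory pathway under endoplasmic reticulum (ER) stress, and caspase-8 starts apoptosis and restrains necroptosis. TNFR1 is the main receptor for the cytokine TNF, and MLKL breaks the plasma membrane in necroptosis. The design asks what each deletion changed, whether the deletions of Xbp1 and Casp8 acted together differently from apart, and which changes of the double knockout were absent in mice that also lacked TNFR1 or MLKL.

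Library totals ran from 3516792.6 to 5823059.7 reads. By group they ran from 3693330 to 4445924.8 in WT, 4316399.5 to 4892575.7 in the Xbp1 knockout, 3516792.6 to 4383486.7 in the Casp8 knockout, 4178825.8 to 5823059.7 in the double knockout, 4308820.8 to 5136443.7 in the TNFR1 triple knockout and 3835605.6 to 5062316.7 in the MLKL triple knockout. Mitochondrially encoded genes took 17.6 ± 1.05% of the reads in WT, 19.8 ± 2.08% in the Xbp1 knockout and 18 ± 0.959% in the Casp8 knockout (SD, n = 5). They took 15.9 ± 3.34% in the double knockout, 19.3 ± 2.54% in the TNFR1 triple knockout and 16.5 ± 2.59% in the MLKL triple knockout. Double knockout replicate 1 stood apart, with 10.3% against 16 to 19.2% in the other double knockout libraries. Its counts spread by 32.6 to 52.4 times a Poisson spread from theirs, which differed among themselves by 7.41 to 14.8 times. A library had a median of 14278.5 genes with at least 10 reads, and 1 read stood for about 0.232 CPM, the reads of a gene scaled to a common library total. The labels gave no sex. Xist and Y-linked genes marked 17 libraries as female and 13 as male, with 1 female in WT, 3 in each single knockout, 1 in the double knockout, 4 in the TNFR1 triple knockout and all 5 in the MLKL triple knockout. The first principal component held 29.4% of the variance and placed WT at −20.3 ± 4.59 and the double knockout at 25.4 ± 11.3 (SD, n = 5), with the means of the other groups between them. Single libraries of other groups lay within the double knockout range of 13.6 to 41.0. These were TNFR1 triple knockout replicate 1 (31.4), the library labelled Xbp1_Casp8_Mlkl_KO replicate 5 (17.2) and Casp8 knockout replicate 4 (15.1). The second component (14.6%) parted the sexes, with every female library at −2.73 or below and every male library at 5.34 or above.

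The targeted genes were read first. Tags of Casp8 (ENSMUSG00000026029, GRCm38 chromosome 1, 58795374 to 58847503) stood at 53.6 ± 2.92 CPM in WT (SD, n = 5; 51.5 to 58.7) and at 30.3 ± 4.44 in the Casp8 knockout (24.7 to 34.8). They stood at 35.9 ± 9.58 in the double knockout (22 to 46.3), at 22 ± 7.12 in the TNFR1 triple knockout (16.5 to 33.6) and at 19.1 ± 6.49 in the MLKL triple knockout (12.2 to 29.6). Casp8 against WT fell in the TNFR1 triple knockout (log2 fold change −1.29 ± 0.235, adjusted p = 0.00345) and in the MLKL triple knockout (−1.49 ± 0.238, adjusted p = 0.00147). The difference did not pass in the Casp8 knockout (−0.82 ± 0.231, adjusted p = 0.0678) or the double knockout (−0.58 ± 0.227, adjusted p = 0.0679). The Xbp1 knockout libraries held 50.9, 21.1, 61.7, 45.0 and 66.8 CPM of Casp8 in replicates 1 to 5. The second of these values, in the library labelled Xbp1_KO replicate 2, came from 91 reads, lay below every Casp8 knockout library and goes against the label. Counts of genes in comparisons with the Xbp1 knockout are therefore also given without this library, while single genes and lists are given with it.

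Mlkl (ENSMUSG00000012519, chromosome 8, 111311797 to 111338177) was at 1.30, 2.76, 4.38, 3.59 and 10.7 CPM in the MLKL triple knockout libraries 1 to 5, with a mean of 4.54 ± 3.62, against 17.9 ± 7.49 in the double knockout and 7.28 ± 1.91 in WT (SD, n = 5). The last value, in the library labelled Xbp1_Casp8_Mlkl_KO replicate 5, lay above every WT library (5.72 to 9.89) and below every double knockout library (11.8 to 29.2). Against WT it goes against the label. The mean log2 CPM of this library over the type I interferon response genes was 6.67, against 2.10 to 2.57 in WT. Xbp1 knockout replicate 5 (6.27) and TNFR1 triple knockout replicate 1 (5.66) held 34.1 and 30.2 CPM of Mlkl. Beside them 10.7 CPM is low, as the label has it. WT is therefore no like comparison for this library, and a wrong label was not tested. Mlkl fell against the double knockout (log2 fold change −1.97 ± 0.454, adjusted p = 0.00669) and did not pass against WT (−0.68 ± 0.485, adjusted p = 0.535), and neither reading changed without this library. Counts of genes in comparisons with the MLKL triple knockout are also given without it, while single genes and lists are given with it. Tnfrsf1a, which encodes TNFR1 (ENSMUSG00000030341, chromosome 6, 125349362 to 125362484), was at 75.4, 61.5, 53.3, 52.4 and 57.7 CPM in the TNFR1 triple knockout, with a mean of 60.1 ± 9.32 against 96.0 ± 16.7 in the double knockout and 70.2 ± 5.35 in WT. It fell against the double knockout (−0.68 ± 0.130, adjusted p = 0.00557), a call that ended in a fit of only the groups compared, and did not pass against WT (−0.23 ± 0.131, adjusted p = 0.381). The fall was not confined to this deletion. Tnfrsf1a rose in the double knockout against WT (0.45 ± 0.129, adjusted p = 0.0122) and fell against the double knockout in the MLKL triple knockout too (−0.42 ± 0.129, adjusted p = 0.0395). The latter call ended without double knockout replicates 1, 4 and 5, the library labelled Xbp1_Casp8_Mlkl_KO replicate 5 and MLKL triple knockout replicates 1 and 2 (adjusted p = 0.0733 to 0.130). Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893) was at 54.8, 54.0, 52.6, 51.1 and 65.2 CPM in the Xbp1 knockout and 100, 75.4, 94.9, 60.3 and 52.8 in WT, and the difference did not pass (−0.47 ± 0.204, adjusted p = 0.313). In the double knockout, which carries the same deletion by its label, Xbp1 was at 104 ± 24.8 CPM (SD, n = 5), higher than in the Xbp1 knockout (0.91 ± 0.203, adjusted p = 0.00558). The deleted exons are not given in the sources used here, 3′ tags can lie outside them, and cells other than epithelium keep IEC-deleted genes. Xbp1 tags therefore check nothing about the Xbp1 deletion, and the other levels are no measure of how complete a deletion was.

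**Figure D1:**
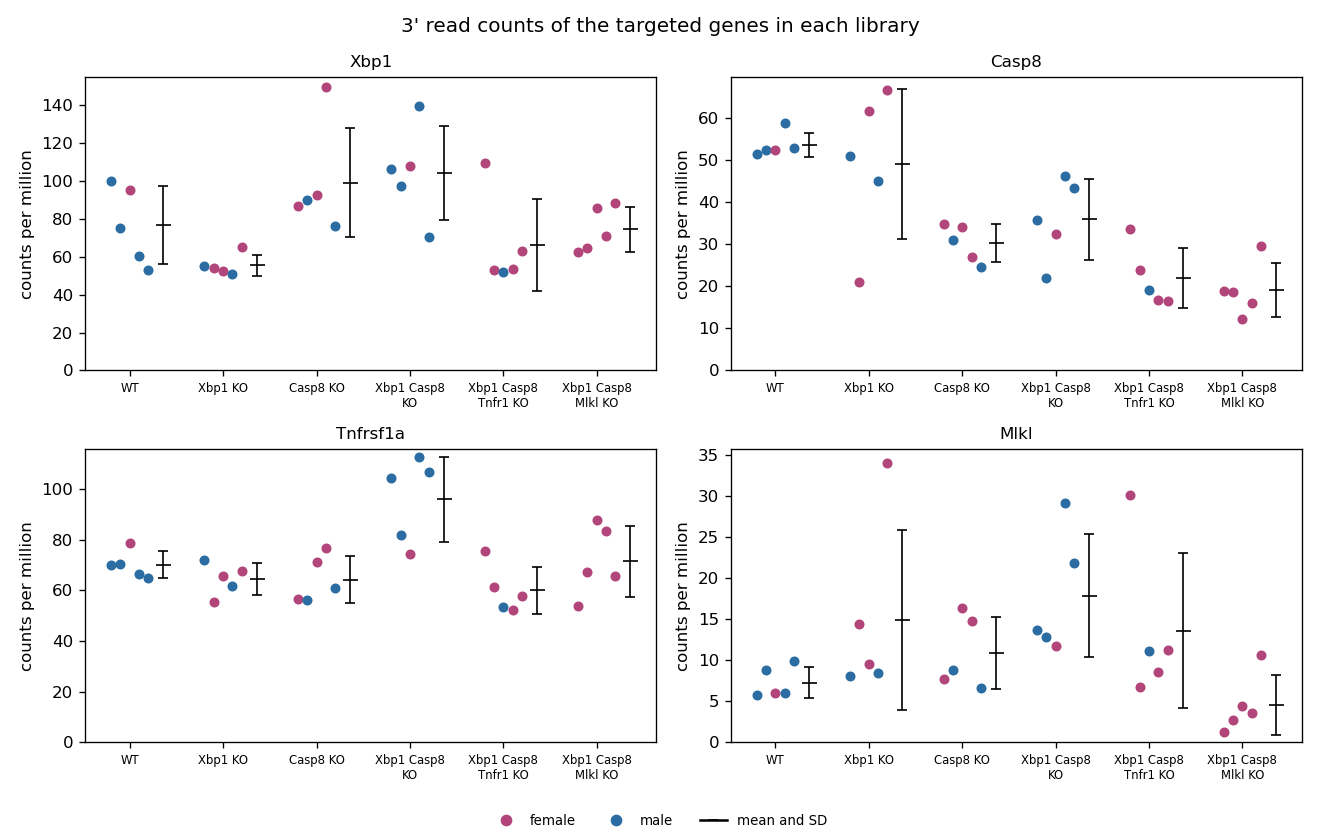
3′ tags of Xbp1, Casp8, Tnfrsf1a and Mlkl in CPM (vertical axes) in each of the 30 libraries, by genotype (horizontal axes). Points are libraries, coloured by the sex read from the data, and bars are the mean with its SD (n = 5). Casp8 ran from 51.5 to 58.7 CPM in WT, and the library labelled Xbp1_KO replicate 2 lay at 21.1.

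Numbers of differing genes are from edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05 over 15458 genes. Values after gene names in parentheses are log2 fold changes ± SE between groups of 5 mice, and adjusted p is from that test unless another is named. For gene lists, the number of members that passed over all genes is followed in parentheses by the number that passed adjusted over the list alone. Members not kept by the low-count filter are left out of these numbers. List calls are from camera with a preset correlation. No list in any comparison passed with an estimated correlation, and that adjusted p stands beside each.

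**Figure D2:**
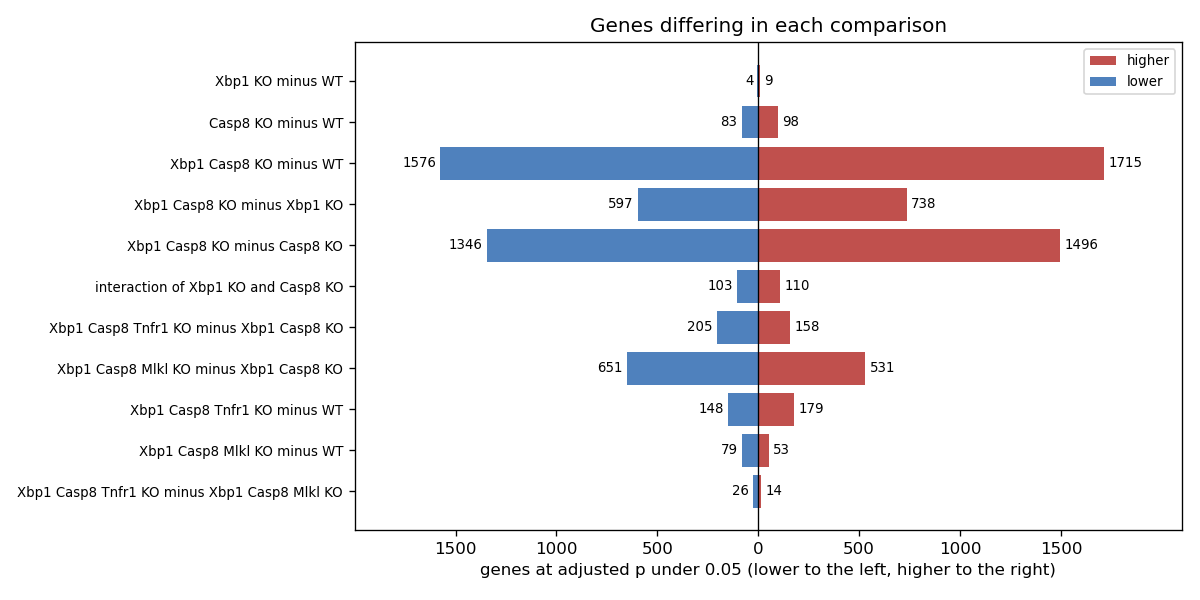
Number of genes that differed in each of the 11 comparisons (horizontal axis, genes at an adjusted p under 0.05), with genes higher and lower in the group named first as separate bars. The double knockout against WT had 3291 differing genes and the Xbp1 knockout against WT 13.

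The Xbp1 knockout was compared with WT to find what the loss of Xbp1 alone changed. Muc2, the main secreted mucin of the colon (chromosome 7, 141690340 to 141754693), fell from 1953 ± 299 CPM in WT to 501 ± 56.9 (SD, n = 5), a log2 fold change of −1.96 ± 0.197 (adjusted p = 5.08e-07). All 5 knockout libraries lay below all 5 WT libraries. Mt1, a metal-binding metallothionein, rose (1.29 ± 0.208, adjusted p = 0.00496), as did Insig1, which restrains cholesterol synthesis (1.43 ± 0.279, adjusted p = 0.0329), and Aqp4, a water channel (1.66 ± 0.342, adjusted p = 0.0372). In all 13 genes differed, 9 higher and 4 lower, and 5 of these by at least 2-fold. By edgeR, 2017 genes had an unadjusted p under 0.05. Of the XBP1 target secretory genes, which fold and export proteins, 0 of 29 measured members rose (3 adjusted over the list alone) and 0 fell (1), with a median of 0.06. For cholesterol synthesis genes 1 of 15 rose (4; median 0.44; adjusted p = 0.301 with an estimated correlation). Type I interferon response genes had a median of 1.83 with 0 of 23 passing (12 adjusted over the list alone; adjusted p = 0.466 with an estimated correlation), and B cell genes a median of 1.63 with 0 of 9 (7; adjusted p = 0.255). The type I interferon median rested largely on Xbp1 knockout replicate 5, whose mean log2 CPM over the list was 6.27 against 2.83 in the next library of its group and a WT mean of 2.30, and the list's call by camera ended without it.

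Without the library labelled Xbp1_KO replicate 2, 6 genes differed between the Xbp1 knockout and WT. The number was also 5, 6 and 8 without Xbp1 knockout replicates 1, 4 and 5, and 4, 4, 2 and 2 without WT replicates 2, 3, 4 and 5. Muc2 and Mt1 passed without each of the 10 libraries in turn, and the Mt1 call ended in males only. The Insig1 call ended without Xbp1 knockout replicates 1, 4 and 5 and WT replicates 1, 2, 3, 4 and 5 (adjusted p = 0.0584 to 0.0913), and the Aqp4 call without the library labelled Xbp1_KO replicate 2, Xbp1 knockout replicates 1 and 4 and WT replicates 2, 3, 4 and 5 (adjusted p = 0.0564 to 0.157). Other settings gave 28 with no low-count filter, 8 with sex in the model, 225 in a fit of only the groups compared, 135 by DESeq2, 424 by limma voom with quality weights and 2 in males only. In males only, 2 Xbp1 knockout mice were set against 4 WT mice, and WT held too few females for a comparison.

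The Casp8 knockout was compared with WT in the same way. Higher in the knockout were Aqp4 (2.29 ± 0.345), the sodium-proton exchanger Slc9a3 (2.07 ± 0.431), the tight junction claudin Cldn4 (1.05 ± 0.208), the guanylyl cyclase C receptor Gucy2c (1.08 ± 0.190) and the keratin Krt36 (3.56 ± 0.733), with adjusted p of at most 0.0116. Ak7, an adenylate kinase (chromosome 12, 105705976 to 105782447), fell from 99.3 ± 44.9 CPM to 0.799 ± 0.696 (SD, n = 5; log2 fold change −6.93 ± 0.701, adjusted p = 5.84e-07). The double and triple knockouts, which lack Casp8 and Xbp1 by label, held 74.1 to 156 CPM of Ak7. Cd59a, which blocks complement lysis (−1.26 ± 0.185), Pcp4, a calmodulin-binding protein (−1.44 ± 0.224), and BC064078 (−4.28 ± 0.648) fell with adjusted p of at most 7.95e-04. In all 181 genes differed, 98 higher and 83 lower, 55 of them by at least 2-fold. Of plasma cell genes 1 of 10 rose (9 adjusted over the list alone; median 1.68). Of immediate early genes, transcribed within minutes of a stimulus, 1 of 9 rose (4; 0.54), and of enteroendocrine genes 2 of 10 (3; 0.31). Of fibroblast genes 1 of 10 fell (5; −0.38). For these lists adjusted p = 0.179 to 0.214 with an estimated correlation.

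Of the 24 genes named by rule that passed in the Casp8 knockout, 16 passed without each library in turn, among them those given above. The count of differing genes between the Casp8 knockout and WT was 88 and 98 without Casp8 knockout replicates 3 and 4, and 94, 111 and 107 without WT replicates 2, 3 and 5. Other settings gave 101 with sex in the model, 435 in a fit of only the groups compared, 356 by DESeq2, 505 by limma voom with quality weights and 24 in males only, the last with 2 Casp8 knockout and 4 WT mice. WT held too few females for a comparison. The calls of Aqp4, Slc9a3, Cldn4, Gucy2c, Krt36, Pcp4 and BC064078 ended in males only, and those of Ak7 and Tgm4 by limma voom. Of the 181 genes, 12 lay within 20 Mb of Tnfrsf1a, Gucy2c and BC064078 among them. Tgm4, a transglutaminase known from the prostate (3.80 ± 0.688, adjusted p = 0.00383), passed as well, with 71.9 and 130 CPM in the male replicates 2 and 5 and 2.30 to 4.83 in the 3 female replicates.

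The double knockout was compared with WT to see what the loss of Xbp1 and Casp8 together changed. Neutrophil, cytokine and antimicrobial genes rose. S100a8 and S100a9, which neutrophils carry in abundance, rose by 7.21 ± 1.17 and 6.12 ± 1.19 on the log2 scale, from 0.327 ± 0.607 to 53.1 ± 61.2 CPM and from 0.611 ± 1.23 to 44.7 ± 55.4 CPM (SD, n = 5). Further rises were seen for the neutrophil chemokine Cxcl2 (5.78 ± 1.13), the cytokine Tnf (4.51 ± 0.895), the antibacterial phospholipase Pla2g2a (4.73 ± 0.673), the protease inhibitor Slpi (4.79 ± 0.781) and the inducible nitric oxide synthase Nos2 (4.82 ± 0.892), with adjusted p of at most 5.77e-04. In all 3291 genes differed, 1715 higher and 1576 lower, 974 of them by at least 2-fold. Among the rises of smallest p were Fam43a, Cwh43, Ddah1, which degrades methylarginines, Emp1, a membrane protein, Lpo, lactoperoxidase, and Serpina3n, an acute-phase protease inhibitor, between 1.56 and 3.79. Among the falls were Pcp4 (−2.29 ± 0.235), Mettl7b (−3.19 ± 0.329), the Wnt ligand Wnt8b (−2.72 ± 0.281), the deiodinase Dio1 (−2.10 ± 0.237) and the calcium pump Atp2b4 (−1.17 ± 0.132), all with adjusted p of at most 1.10e-06.

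By list, interferon gamma response and antigen presentation genes rose in the double knockout for 27 of 27 (27 adjusted over the list alone; median 2.52), with examples in Cd74 (2.69 ± 0.384), H2-DMa (2.40 ± 0.350), H2-Ab1 (2.10 ± 0.325) and H2-DMb1 (2.96 ± 0.460), which load and present peptides on MHC class II. Plasma cell genes rose for 10 of 10 (10; median 3.30), with Mzb1 (3.35 ± 0.399), Jchain (3.58 ± 0.501) and Igha (3.48 ± 0.533), which serve antibody secretion. Neutrophil genes rose for 4 of 4 measured (4; median 4.20), of 15 listed. T and NK cell genes rose for 8 of 8 measured (8; median 2.59), of 16 listed, with the T cell receptor constant gene Trac (3.62 ± 0.662) and Cd2 (2.48 ± 0.485). A gene almost absent in WT could pass the low-count filter through the double knockout alone. The shares of these 2 lists that rose are therefore not independent of the filter. Monocyte and macrophage genes rose for 12 of 16 (12; median 1.11), with Ly6c2 (4.08 ± 0.704). Of epithelial antimicrobial genes 11 of 13 (11; median 2.15) rose and 1 fell, and of inflammatory cytokines and NF-kB targets 13 of 16 (14; median 1.30) rose. Cholesterol synthesis genes rose for 12 of 15 (13; median 0.85), with Insig1 (1.40 ± 0.279). Immediate early genes rose for 8 of 9 (8; median 0.98), with Fosb (2.35 ± 0.393) and Egr1 (1.62 ± 0.303). Enteroendocrine genes rose for 4 of 10 (5; median 0.56), with the hormone genes Sct (1.78 ± 0.238) and Gcg (0.89 ± 0.165). ATF4 integrated stress response genes rose for 7 of 16 (7; median 0.56), with asparagine synthetase Asns (1.19 ± 0.190) and the cystine transporter Slc7a11 (1.68 ± 0.395). XBP1 target secretory genes rose for 7 of 29 (8; median 0.20), with Herpud1 (0.75 ± 0.154) and Edem1 (0.66 ± 0.141), which clear misfolded proteins from the ER, and the list's call ended without double knockout replicate 3. The XBP1 target, ATF4 and cholesterol lists were read in the same tissue RNA in which the plasma cell markers rose by a median of 3.30. For the lists that rose, adjusted p = 5.53e-18 to 0.0156 with the preset correlation and adjusted p = 0.179 to 0.475 with an estimated correlation.

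Smooth muscle genes fell in the double knockout for 12 of 12 (12 adjusted over the list alone; median −1.07), with desmin Des (−1.53 ± 0.203) and myosin light chain kinase Mylk (−1.41 ± 0.174). Fibroblast genes fell for 6 of 10 (8; median −0.65), with the matrix proteins Lum (−1.15 ± 0.246) and Dpt (−0.81 ± 0.177). Enteric neuron and glia genes fell for 4 of 9 (5; median −0.66), with glial S100b (−1.74 ± 0.300). For these lists adjusted p = 4.34e-18 to 0.00174 with the preset correlation and adjusted p = 0.179 to 0.301 with an estimated correlation. Muc2 fell (−1.49 ± 0.194), to 697 ± 186 CPM. Members that rose and fell, with the numbers adjusted over the list alone in parentheses, were for ER stress sensors and chaperones 1 and 0 of 10 (1 and 0), goblet cell 2 and 4 of 15 (3 and 4), absorptive colonocyte 4 and 2 of 15 (4 and 2) and type I interferon response 2 and 0 of 23 (0 and 0). Further numbers were for cell death machinery other than the targeted genes 8 and 3 of 17 (8 and 3), stem cell and WNT targets 3 and 2 of 15 (3 and 3), proliferation 5 and 0 of 25 (5 and 0), epithelial regeneration 4 and 0 of 10 (5 and 1) and tissue remodelling 3 and 2 of 13 (8 and 2). The numbers were for fatty acid oxidation and ketogenesis 0 and 1 of 14 (0 and 1), xenobiotic metabolism 2 and 3 of 15 (2 and 4), tuft cell 0 and 0 of 5 (0 and 0), B cell 0 and 0 of 9 (0 and 0) and eosinophil and mast cell 1 and 0 of 2 (1 and 1). They were for endothelium 0 and 1 of 9 (0 and 1), adipose 0 and 0 of 6 (0 and 0), small intestine and Paneth cell 0 and 1 of 3 (0 and 1), squamous epithelium 1 and 0 of 3 (1 and 0) and mitochondrially encoded 0 and 3 of 6 (0 and 4).

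The count of genes differing between the double knockout and WT moved by less than 1.5-fold in all settings tried and without any 1 library (2580 to 3383). In males only, 4 against 4 mice, it was 2634. Each group held 1 female, too few for a comparison in females. Of the 82 genes named by rule that passed, 76 passed without each library in turn. Among type I interferon response genes, 2 of 23 rose (0 adjusted over the list alone; adjusted p = 0.570 with an estimated correlation). A member that rose was Oasl2 (2.87 ± 0.984), whose call ended without double knockout replicates 4 and 5 and WT replicates 1, 2, 3, 4 and 5 (adjusted p = 0.0512 to 0.0990). Another was Ifit1 (3.44 ± 1.26), whose call ended without double knockout replicates 1, 2, 4 and 5 and WT replicates 1, 2, 3, 4 and 5 (adjusted p = 0.0527 to 0.0958).

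**Figure D3:**
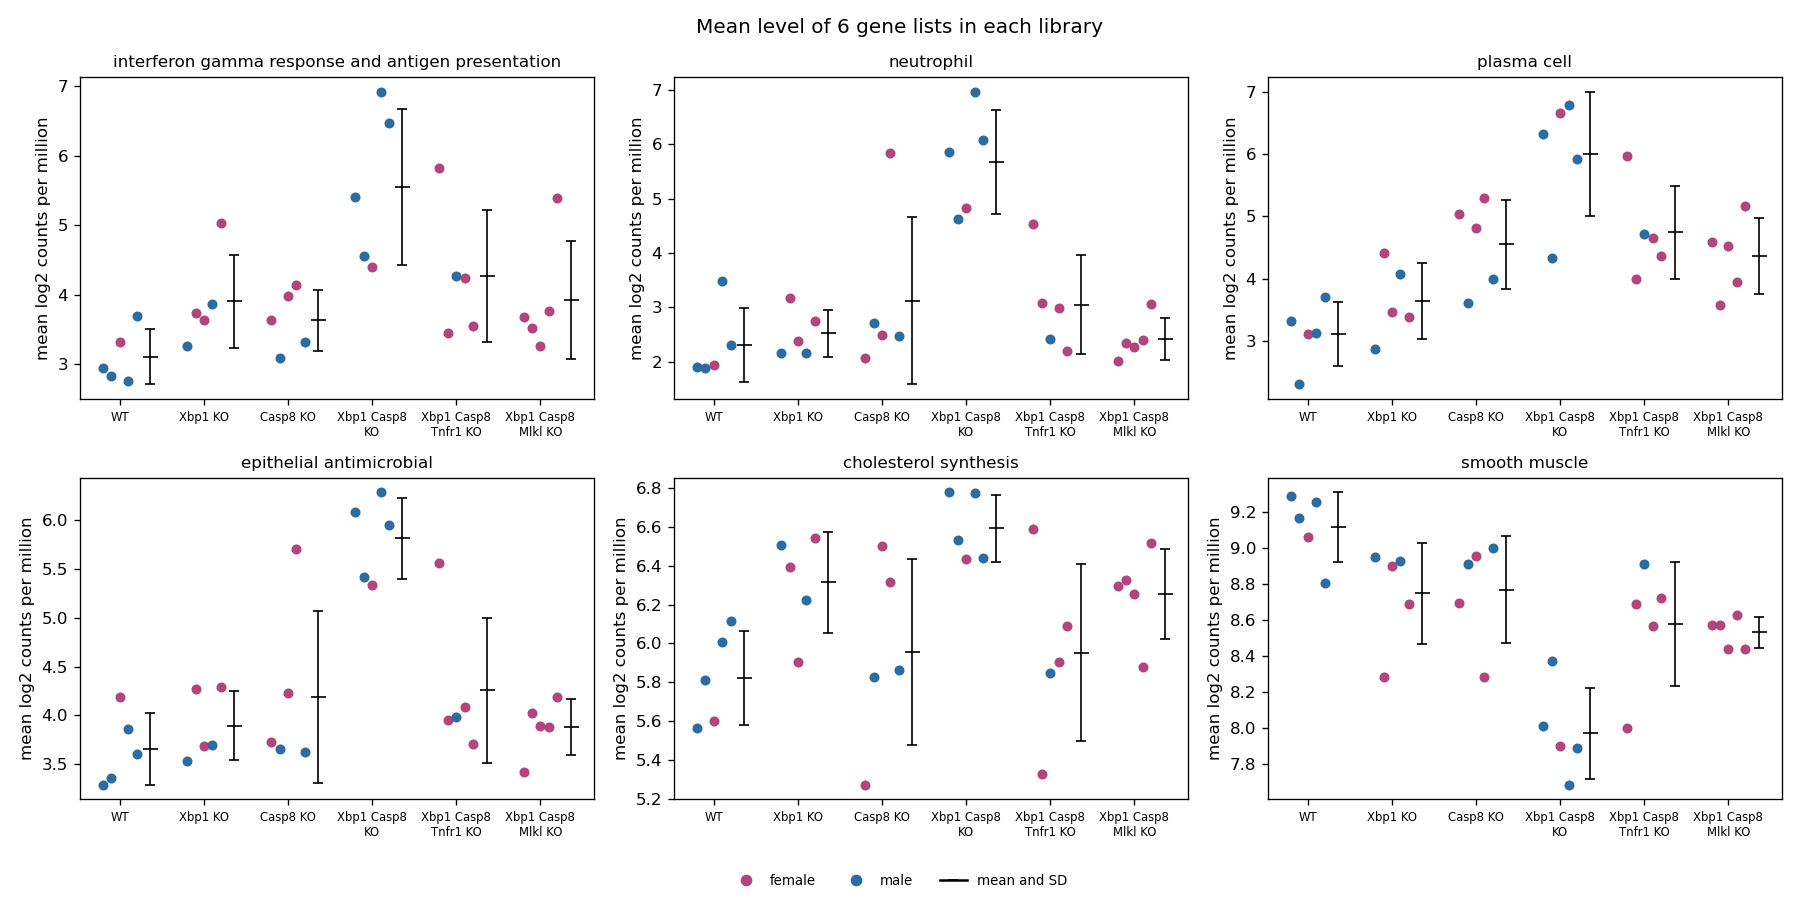
Mean log2 CPM of the measured members of 6 gene lists (vertical axes) in each of the 30 libraries by genotype (horizontal axes). Points are libraries and bars the mean with its SD (n = 5). Smooth muscle genes had a median log2 fold change of −1.07 in the double knockout against WT, and interferon gamma response genes one of 2.52.

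The double knockout was then set against each single knockout. Against the Xbp1 knockout, a group that included the library labelled Xbp1_KO replicate 2, S100a8 (7.25 ± 1.17), Cxcl9, a chemokine for T cells (5.25 ± 0.994), Nos2 (5.24 ± 0.932), Il1b (4.40 ± 0.870) and Serpina3n (2.86 ± 0.392) rose. Mettl7b (−2.90 ± 0.330), Dio1 (−1.69 ± 0.238), the transglutaminase Tgm3 (−1.37 ± 0.201) and Pcp4 (−1.56 ± 0.239) fell, all of these with adjusted p of at most 0.00237. Interferon gamma response genes rose for 14 of 27 (23 adjusted over the list alone; median 1.54), plasma cell genes for 9 of 10 (10; median 2.54) and epithelial antimicrobial genes for 9 of 13 (11; median 2.15). Cytokines and NF-kB targets rose for 9 of 16 (13; median 1.21) and monocyte and macrophage genes for 7 of 16 (11; median 0.83). Smooth muscle genes fell for 9 of 12 (12; median −0.79). For these lists adjusted p = 0.179 to 0.301 with an estimated correlation. In all 1335 genes differed, 738 higher and 597 lower. Without the library labelled Xbp1_KO replicate 2 there were 1354. The count was 822 and 748 without Xbp1 knockout replicates 1 and 4, and 808 and 842 without double knockout replicates 1 and 4. It was 797 in a fit of only the groups compared and 737 in males only, the last from 4 against 2 mice, with too few females in the double knockout for a comparison. Of 65 named genes that passed, 53 passed without each library in turn, among them those given here.

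Against the Casp8 knockout, the double knockout had higher Ak7 (7.21 ± 0.697), Krt20, a keratin of mature colonocytes (1.09 ± 0.162), the lysosomal protease gene Lgmn (1.39 ± 0.200), Ido1, an interferon-induced enzyme of tryptophan breakdown (4.93 ± 0.860) and the siderophore-binding Lcn2 (2.80 ± 0.563). It had lower Igsf9 (−1.13 ± 0.114), Mettl7b (−3.15 ± 0.330), the actin-binding Cald1 (−1.15 ± 0.126) and Tgm3 (−1.69 ± 0.203), all of these with adjusted p of at most 0.00102. The Ak7 difference rests on its low level in the Casp8 knockout (at most 1.73 CPM), since WT held 48.9 to 150 CPM and the double knockout 110 to 129. Interferon gamma response genes rose for 21 of 27 (27 adjusted over the list alone; median 1.96), monocyte and macrophage genes for 12 of 16 (15; median 1.03) and plasma cell genes for 8 of 10 (8; median 1.49). Epithelial antimicrobial genes rose for 7 of 13 (7; median 1.61), while smooth muscle genes fell for 9 of 12 (10; median −0.68). For the lists given here, adjusted p = 0.179 to 0.335 with an estimated correlation. In all 2842 genes differed, 1496 higher and 1346 lower, and no single library moved that count by over 1.5-fold. It was 1570 in a fit of only the groups compared and 1298 in males only, the last from 4 against 2 mice, with too few females in the double knockout. Of 56 named genes that passed, 50 passed without each library in turn, among them those given here.

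Whether the effect of Xbp1 loss differed with and without Casp8 was tested as an interaction, which compares the double knockout minus the Casp8 knockout with the Xbp1 knockout minus WT. Mettl7b (−2.86 ± 0.430), Igsf9 (−1.37 ± 0.161), the sugar phosphate transporter gene Slc37a2 (−2.08 ± 0.375) and Tgm3 (−1.55 ± 0.281) had a lower interaction term. Ak7 (7.55 ± 0.838) and the mitochondrial tRNA gene mt-Tq (2.22 ± 0.428) had a higher one, all of these with adjusted p of at most 0.0128. The Ak7 term rests on the Casp8 knockout, with at most 1.73 CPM. The double and triple knockouts, which also lack Casp8 by label, held 74.1 to 156 CPM. An effect of Xbp1 loss on Ak7 cannot be told apart from a trait of the Casp8 knockout mice, such as litter or line, which was not tested. In all 213 genes passed, 110 with a positive and 103 with a negative term. Of B cell genes none passed over all genes and 5 of 9 passed with a negative term adjusted over the list alone (median −2.69; adjusted p = 0.335 with an estimated correlation). Of smooth muscle genes 1 of 12 passed (2; −0.48; adjusted p = 0.436). By edgeR, 2808 genes had an unadjusted p under 0.05. Of 18 named genes that passed, 16 passed without each library in turn, among them these 6. The call of Ak7 ended by limma voom. The count rested on single libraries. It was 47, 88, 112, 465 and 41 without Casp8 knockout replicates 1, 2, 3, 4 and 5. It was 92 without the library labelled Xbp1_KO replicate 2 and 57, 83, 59 and 137 without Xbp1 knockout replicates 1, 3, 4 and 5. It was 58, 429, 420, 133 and 90 without double knockout replicates 1, 2, 3, 4 and 5 and 80, 107, 96 and 60 without WT replicates 2, 3, 4 and 5. In other settings it was 122 with a stricter low-count filter, 73 with the replicate number as a block, 55 with sex in the model, 107 in a fit of only the groups compared, 495 by DESeq2, 411 by limma voom with quality weights and 37 in males only, with too few females in WT and the double knockout for a comparison.

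Genes called in a single knockout were compared with those of the double knockout, both against the same WT libraries. All 13 genes that differed in the Xbp1 knockout, Muc2 and Mt1 among them, differed in the same direction in the double knockout, where independent lists would share 1.41. Of the 181 genes of the Casp8 knockout, 91 did so and 3 differed in opposite directions, where independent lists would share 19.3. In 40 simulations of unchanged groups against these controls, the highest shared number was 0 for the Xbp1 and 0 for the Casp8 knockout. Unchanged groups give almost no calls that could be shared, so this does not measure what the shared WT libraries add to the overlap of real changes. With the WT libraries split between the comparisons in 20 ways, the shared numbers were 1 to 6 (median 1) and 1 to 19 (median 9). The single knockouts also had fewer calls in such splits. As examples, 4 of 6 genes called were shared in a split for the Xbp1 knockout, and 13 of 55 in another for the Casp8 knockout. The covariance of fold changes over all genes was 0.148 against a simulated 0.0361 for the Xbp1 knockout, and 0.144 against 0.0360 for the Casp8 knockout. For the Xbp1 knockout leaving out 1 library in turn gave 2 to 20 (6 without the library labelled Xbp1_KO replicate 2, 5, 6 and 8 without Xbp1 knockout replicates 1, 4 and 5, 20 without double knockout replicate 1, and 4, 4, 2 and 2 without WT replicates 2, 3, 4 and 5). Other settings gave 110 by DESeq2, 152 in a fit of only the groups compared, 8 with sex in the model and 297 by limma voom with quality weights. For the Casp8 knockout leaving out 1 library in turn gave 32 to 153 (43 and 32 without Casp8 knockout replicates 3 and 4, 153 without double knockout replicate 1, and 60, 37, 56, 56 and 54 without WT replicates 1, 2, 3, 4 and 5). Other settings gave 164 by DESeq2, 177 in a fit of only the groups compared, 48 with sex in the model and 231 by limma voom with quality weights.

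The TNFR1 triple knockout was compared with the double knockout to ask which changes depended on TNFR1. S100a8 fell from 53.1 ± 61.2 to 1.04 ± 1.61 CPM (SD, n = 5; log2 fold change −5.69 ± 0.993). Serpina3n (−2.35 ± 0.377), Emp1 (−1.28 ± 0.187), the hormone gene Sct (−1.48 ± 0.231) and the kinase gene Stk38l (−1.59 ± 0.263) fell. Mettl7b (2.60 ± 0.331), Pcp4 (1.29 ± 0.240), Dio1 (1.50 ± 0.239) and BC064078 (4.66 ± 0.583) rose, all of these with adjusted p of at most 0.00474. These 9 genes passed without each library in turn. In all 363 genes differed, 158 higher and 205 lower, and 24 of them, Emp1 and BC064078 included, lay within 20 Mb of Tnfrsf1a. Among the lists, 3 of 27 interferon gamma response genes fell (19 adjusted over the list alone; median −1.29), and 4 of 13 (10; median −1.72) epithelial antimicrobial genes. So did 1 of 10 (9; median −1.27) plasma cell genes, 2 of 15 (12; median −0.68) cholesterol synthesis genes and 4 of 15 (7; median −0.30) goblet cell genes, while 6 of 12 (10; median 0.67) smooth muscle genes rose. For these lists adjusted p = 0.179 to 0.335 with an estimated correlation. An example was Ido1 (−2.98 ± 0.667), whose call ended without TNFR1 triple knockout replicates 2, 4 and 5 and double knockout replicate 4 (adjusted p = 0.0521 to 0.106). Another was Mylk (0.79 ± 0.172), whose call ended without TNFR1 triple knockout replicate 2 and double knockout replicate 4 (adjusted p = 0.0518 to 0.0547).

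The number of genes differing between the TNFR1 triple and the double knockout rested on single libraries. It was 931, 63, 167, 130 and 111 without TNFR1 triple knockout replicates 1, 2, 3, 4 and 5, and 97, 733, 569, 99 and 149 without double knockout replicates 1, 2, 3, 4 and 5. Of 43 named genes that passed, 17 passed without each library in turn. In a fit of only the groups compared, 21 genes differed, and the call of Dio1 ended. That of S100a8 ended by limma voom. With sex in the model, 197 of the 363 genes still passed, with a median ratio of fold changes with and without the term of 1.02 and of SEs of 1.09. Neither sex could be compared alone, since the TNFR1 triple knockout held 1 male and the double knockout 1 female.

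The MLKL triple knockout was compared with the double knockout to ask the same of MLKL. Nos2 fell from 16.7 ± 13.8 to 0.431 ± 0.329 CPM (SD, n = 5; log2 fold change −5.22 ± 0.933). Cxcl2 (−6.49 ± 1.23), S100a9 (−7.18 ± 1.33), Slpi (−3.84 ± 0.732), Hbegf, a growth factor for epithelium (−1.61 ± 0.224), Krt20 (−1.05 ± 0.162) and Serpina3n (−2.92 ± 0.395) fell as well, all with adjusted p of at most 0.00137. The goblet cell gene Clca1 (1.50 ± 0.185), Dio1 (1.91 ± 0.237), Mettl7b (2.57 ± 0.332), the prolactin receptor gene Prlr (1.95 ± 0.296) and the gasdermin gene Gsdmc3 (1.85 ± 0.265) rose, with adjusted p of at most 2.58e-04. In all 1182 genes differed, 531 higher and 651 lower. Interferon gamma response genes fell for 14 of 27 (21 adjusted over the list alone; median −1.57), with Cd74 (−2.14 ± 0.374) and H2-DMa (−1.90 ± 0.336). Plasma cell genes fell for 8 of 10 (10; median −1.86), with Mzb1 (−1.96 ± 0.352) and Derl3 (−2.11 ± 0.476). Epithelial antimicrobial genes fell for 9 of 13 (9; median −1.86), with Lcn2 (−2.96 ± 0.562) and Pla2g2a (−3.15 ± 0.572). Cytokines and NF-kB targets fell for 9 of 16 (10; median −1.30), with Nfkbia (−0.95 ± 0.151) and Cxcl5 (−2.36 ± 0.410). Neutrophil genes fell for 4 of 4 measured (4; median −4.52), of 15 listed. Monocyte and macrophage genes fell for 5 of 16 (8; median −0.65), with Ms4a7 (−1.27 ± 0.244). Smooth muscle genes rose for 8 of 12 (9; median 0.58), with Acta2 (0.72 ± 0.162) and Mylk (0.73 ± 0.172). For these lists adjusted p = 0.179 to 0.293 with an estimated correlation. The genes given here passed without each library in turn, as did 50 of the 66 named genes that passed. The count was 720 and 781 without double knockout replicates 4 and 5. It was 490 in a fit of only the groups compared. Without the library labelled Xbp1_Casp8_Mlkl_KO replicate 5 it was 1239. With sex in the model, 700 of the 1182 genes still passed and 1178 kept their direction, with a median ratio of fold changes with and without the term of 1.04 (quartiles 0.903 to 1.15) and of SEs of 1.16. All MLKL triple knockout mice were female and 1 double knockout mouse was, so that neither sex could be compared alone.

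Genes that had changed in the double knockout against WT were looked up in the triple knockouts against the double knockout. In the TNFR1 triple knockout 305 of them passed in the opposite direction (9.27% of 3291, and 84.0% of the 363 genes that differed there), 161 of these higher in the double knockout, and 1 passed in the same direction. In the MLKL triple knockout 925 did (28.1%, and 78.3% of 1182), 515 of these higher in the double knockout, and 0 in the same direction. S100a8, Serpina3n, Mettl7b, Dio1 and Mylk were among the genes that passed in opposite directions in both. Both comparisons share the double knockout libraries. Independent lists would share 38.9 and 126 genes. In 40 simulations of unchanged groups the highest shared number was 0 in both, which again does not measure what the shared libraries add where real changes are called. With the double knockout libraries split in 20 ways, the numbers were 4 to 279 (median 65) and 12 to 462 (median 278.5). The genes called in the triple against the double knockout changed as well. For TNFR1 the 279 were of 801 called and the 4 of 4, and for MLKL the 462 were of 1146 and the 12 of 13. Fewer libraries and the loss of shared ones therefore cannot be told apart in these numbers. The covariances of fold changes were −0.170 and −0.224 against simulated values of −0.0355 and −0.0356. For the TNFR1 triple knockout leaving out 1 library in turn gave 53 to 777 (777, 53, 131, 117 and 97 without TNFR1 triple knockout replicates 1, 2, 3, 4 and 5, and 88, 575, 481, 87 and 128 without double knockout replicates 1, 2, 3, 4 and 5). For the MLKL triple knockout leaving out 1 library in turn gave 562 to 1051 (562 without double knockout replicate 4), and 938 passed without the library labelled Xbp1_Casp8_Mlkl_KO replicate 5. In fits of only the groups compared, the numbers were 19 and 428.

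Against WT, the TNFR1 triple knockout had lower Muc2 (430 ± 189 CPM, log2 fold change −2.18 ± 0.199), Ank1, an ankyrin (−1.60 ± 0.226), Wnt8b (−1.37 ± 0.253), the lymphatic marker Lyve1 (−1.27 ± 0.251) and Casp8. It had higher Aqp4 (2.53 ± 0.347), Lpo (3.14 ± 0.496), Cldn4 (1.24 ± 0.207), Krt36 (4.09 ± 0.720) and the T cell surface gene Cd2 (2.76 ± 0.477), all of these with adjusted p of at most 0.00717. These genes passed without each library in turn, as did 17 of the 36 named genes that passed. In all 327 genes differed, 179 higher and 148 lower. Plasma cell genes rose for 6 of 10 (9 adjusted over the list alone; median 2.014), interferon gamma response genes for 5 of 27 (14; median 1.37) and T and NK cell genes for 1 of 8 (6; median 2.10). TNFR1 triple knockout replicate 1 had a mean log2 CPM of 5.83 over the interferon gamma list, against 4.27 in the next library of its group. Goblet cell genes fell for 4 of 15 (5; median −0.29) and smooth muscle genes for 2 of 12 (9; median −0.57). For these lists adjusted p = 0.179 to 0.319 with an estimated correlation. An example was Mzb1 (1.98 ± 0.417), whose call ended with sex in the model and without TNFR1 triple knockout replicate 1 (adjusted p = 0.0552). Another was the goblet cell peptide Tff3 (−0.66 ± 0.145), whose call ended without TNFR1 triple knockout replicate 4 (adjusted p = 0.0524). The count was 77, 507 and 129 without TNFR1 triple knockout replicates 1, 3 and 4, and 169, 136, 141 and 214 without WT replicates 1, 2, 4 and 5. It was 74 with sex in the model, 560 by DESeq2 and 836 by limma voom with quality weights. WT held 1 female and the TNFR1 triple knockout 1 male, so that neither sex could be compared alone.

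The MLKL triple knockout against WT had lower Muc2 (649 ± 72.2 CPM, log2 fold change −1.59 ± 0.195), Ank1 (−1.61 ± 0.227), Nbea, a vesicle trafficking protein (−1.01 ± 0.155), BC064078 (−3.90 ± 0.601) and Casp8 (−1.49 ± 0.238), with adjusted p of at most 0.00147. These passed without each library in turn and with sex in the model. In all 132 genes differed, 53 higher and 79 lower, and 10 of them, BC064078 and Gucy2c included, lay within 20 Mb of Tnfrsf1a. Among the rises, that of Gucy2c (1.04 ± 0.189) ended without MLKL triple knockout replicate 3 (adjusted p = 0.0554) and that of Lpo (2.61 ± 0.512) without MLKL triple knockout replicate 3 (adjusted p = 0.0554). Of smooth muscle genes 3 of 12 (11 adjusted over the list alone; median −0.59) fell and of type I interferon response genes 2 of 23 (22; median 2.55) rose. Plasma cell genes had none past the threshold over all genes (7 of 10 adjusted over the list alone; median 1.43). Over these lists, adjusted p = 0.179 to 0.339 with an estimated correlation. By edgeR, 2373 genes had an unadjusted p under 0.05. The library labelled Xbp1_Casp8_Mlkl_KO replicate 5 stood apart in the type I interferon list, with a mean log2 CPM of 6.67 against 3.57 in the next library of its group. Of 26 named genes that passed, 6 passed without each library in turn. The count was 131 without that library, and 43, 9 and 59 without MLKL triple knockout replicates 2, 3 and 4, and 36, 25, 34 and 70 without WT replicates 1, 2, 4 and 5. It was 209 with no low-count filter, 11 with sex in the model, 306 in a fit of only the groups compared, 291 by DESeq2 and 350 by limma voom with quality weights. WT held 1 female and the MLKL triple knockout no male, so that neither sex could be compared alone.

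Between the triple knockouts, the TNFR1 triple knockout had lower Clca1 (−1.25 ± 0.184), Tff3 (−0.82 ± 0.145), the C-type lectin gene Clec2h (−1.12 ± 0.202), the pentraxin gene Mptx1 (−2.18 ± 0.386), Stk38l (−1.77 ± 0.263) and Rhno1, a DNA damage protein (−1.23 ± 0.166). It had higher Mucl1 (4.08 ± 0.683), Tiam1, an activator of Rac (1.30 ± 0.235), and Syt8, a synaptotagmin (1.36 ± 0.248), all of these with adjusted p of at most 0.00520. These passed without each library in turn, as did 14 of the 17 named genes that passed. In all 40 genes differed, 14 higher and 26 lower, and 9 of them, Rhno1 and Clec2h included, lay within 20 Mb of Tnfrsf1a. Goblet cell genes fell for 2 of 15 (8 adjusted over the list alone; median −0.50), with an adjusted p = 0.104 with an estimated correlation. Of interferon gamma response genes 0 of 27 passed (0 adjusted over the list alone; median 0.36; adjusted p = 0.636 with an estimated correlation), and the median turned to −0.46 without TNFR1 triple knockout replicate 1. Of type I interferon response genes 0 of 23 passed (0 adjusted over the list alone; median −0.81; adjusted p = 0.712 with an estimated correlation), and the median turned to 0.48 without the library labelled Xbp1_Casp8_Mlkl_KO replicate 5, when 54 genes differed. By edgeR 1321 genes in all had an unadjusted p under 0.05. The count was 20 without TNFR1 triple knockout replicate 4, and 21 and 25 without MLKL triple knockout replicates 3 and 4. It was 72 with no low-count filter, 19 in a fit of only the groups compared, 86 by DESeq2, 36 in females only and 26 without genes near the targeted loci. The comparison in females set 4 against 5 mice.

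**Figure D4:**
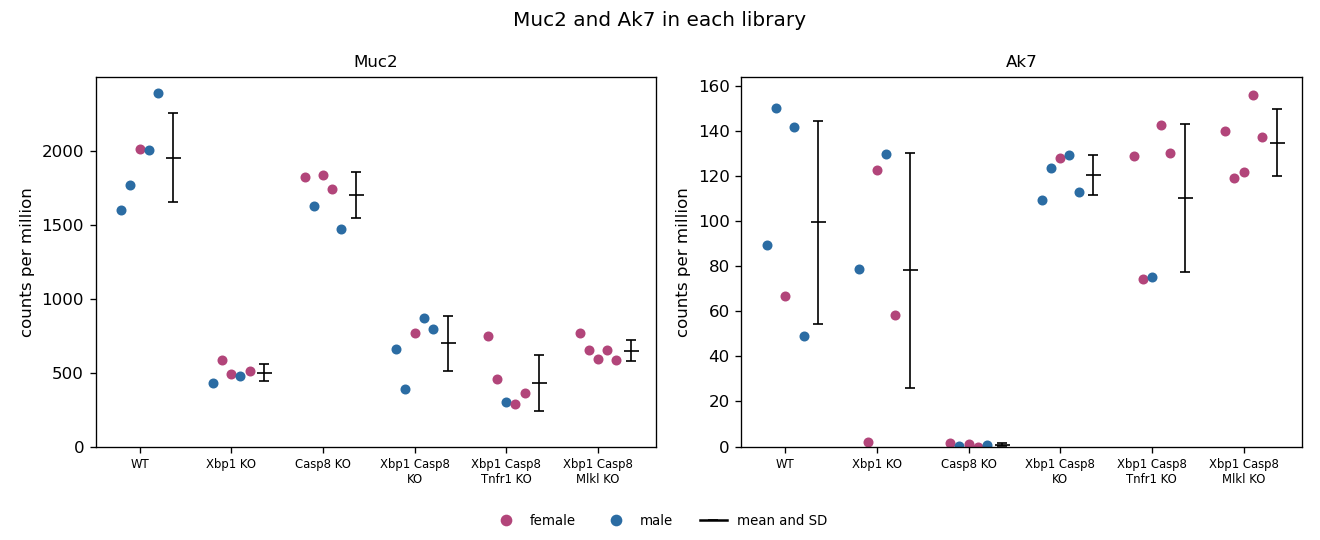
CPM of Muc2 and Ak7 (vertical axes, as labelled) in each of the 30 libraries by genotype (horizontal axes). Points are libraries, and bars are the mean with its SD (n = 5). Muc2 was 1953 ± 299 CPM in WT and 501 ± 56.9 in the Xbp1 knockout, and Ak7 0.799 ± 0.696 in the Casp8 knockout.

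Reads could be divided between genes in the deposited counts, so genes that overlap or share sequence are uncertain. Of the genes named, this holds for those with many values that are not whole. They are Mylk (66.7% of its values), Des (40% of its values), Ank1 (66.7% of its values), Pcp4 (50% of its values), Rhno1 (56.7% of its values), Mettl7b (36.7% of its values), Mzb1 (33.3% of its values) and mt-Tq (53.3% of its values). Members of gene families with similar sequences, such as the class II histocompatibility, immunoglobulin, S100 and gasdermin C genes, could be uncertain in the same way, which was not tested.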

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

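Tests chosen only after the result was seen were those of a swap and of counting noise for the low Casp8 and the enrichment tests near Casp8. So were those near Tnfrsf1a between the triple knockouts and in the Casp8 knockout and both triple knockouts against WT. The comparisons of Muc2 and Ak7 between libraries were chosen then too. Of 234 groups of 5 libraries tested for a library far from the others (targeted genes, totals and list scores, the mean log2 CPM of a list), 23 had one at Dixon's critical value of 0.71, where chance gives about 1 in 20.

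Highest and lowest values in this paragraph are those within the 5 libraries of the genotype named, and other genotypes can lie beyond them. Within WT, Casp8 was highest in replicate 4 (58.7 CPM), which also had the highest neutrophil score of WT (3.48). In the Xbp1 knockout, replicate 3 had the most reads (4893000), and replicate 5 had the highest Xbp1 (65.2 CPM), Mlkl (34.1 CPM), type I interferon score (6.27) and proliferation score (5.23). The library labelled Xbp1_KO replicate 2 had the lowest enteric neuron and glia score of the Xbp1 knockout (2.56). Within the Casp8 knockout, replicate 4 had the highest Xbp1 (149 CPM), cytokine and NF-kB score (4.49) and neutrophil score (5.84). Within the TNFR1 triple knockout, replicate 1 stood apart in Xbp1 (109 CPM), Mlkl (30.2 CPM), the scores of ER stress genes (7.26), antimicrobial genes (5.56) and type I interferon genes (5.66), all highest in that group. It had the lowest fibroblast (6.45) and enteric neuron scores (2.11) of that group. In the MLKL triple knockout, replicate 2 had the most reads (5062000) and the highest small intestine and Paneth cell score (3.75) and replicate 3 the lowest mitochondrially encoded score (11.9). The library labelled Xbp1_Casp8_Mlkl_KO replicate 5 had the highest type I interferon (6.67) and interferon gamma scores (5.40). By the interaction test, 213 genes had an Xbp1 effect that differed with and without Casp8, a count that rested on single libraries.

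The library labelled Xbp1_KO replicate 2 had 91 reads of Casp8, and their upper 95% Poisson limit of 25.9 CPM lay under the 45.0 CPM of the lowest other Xbp1 knockout library, which argues against counting noise. A swap with a Casp8 knockout library would need a partner there, but the highest Casp8 among them was 34.8 CPM, which argues against that swap. Swaps with libraries of other groups were not tested. Over 146 genes that differed between the Casp8 knockout and WT in a fit without the Xbp1 knockout (and without Casp8 and genes whose library values had been seen), its median position on the way from WT (0) to the Casp8 knockout (1) was 0.523. The other Xbp1 knockout libraries lay at 0.143 to 0.322, so a wrong label could give this value. Double knockout libraries, which lack Casp8 by label, ran from 0.375 to 0.723, a range that holds it. Triple knockout libraries, labelled as lacking Casp8 too, ran from 0.204 to 0.670, so the position does not mark the deletion alone. Its Muc2 of 587 CPM lay under the 1468 to 1836 CPM of the Casp8 knockout, against that genotype, and its Ak7 of 1.85 CPM under the 110 to 129 CPM of the double knockout. A wrong label stays open without a genotype that accounts for Casp8, Muc2 and Ak7 together, and no biological explanation was tested.

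Genes that differed between the triple knockouts lay near Tnfrsf1a more often than elsewhere (9 of 40 within 20 Mb, odds ratio 17, 95% interval 7.04 to 37.0, Fisher's exact p = 2.12e-08). Variants of another strain linked to the engineered allele could give this. Against WT, however, the TNFR1 triple knockout, which carries that allele by label, showed no enrichment (odds ratio 1.06, 0.383 to 2.37, Fisher's exact p = 0.829). The same window was enriched in comparisons without that allele. By Fisher's exact test these were the double knockout against WT (odds ratio 1.50, 1.14 to 1.97, p = 0.00409), the Casp8 knockout against WT (odds ratio 4.17, p = 7.66e-05) and the MLKL triple knockout against WT (odds ratio 4.79, 2.21 to 9.24, p = 1.01e-04). These values argue against variants linked to that allele as the whole account. Neighbouring genes that move with tissue state may add to it, and variants linked to other alleles were not tested in this window. By the same Fisher's exact test, calls near Casp8 in the Casp8 knockout (odds ratio 1.93, 0.612 to 4.65, p = 0.196) and near Mlkl in the MLKL triple knockout against the double knockout (odds ratio 0.714, 0.416 to 1.15, p = 0.201) leave the question open. For these the bound first written down, a p that misses the threshold, was wrong, because the interval near Casp8 still allows an enrichment of over 4-fold and that near Mlkl one above 1, and the reading was changed after the values were seen.

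With sex as a term, 74 genes differed between the TNFR1 triple knockout and WT in place of 327, and 11 between the MLKL triple knockout and WT in place of 132. For the TNFR1 triple knockout the median ratio of the log2 fold changes with and without the term was 0.914 (quartiles 0.843 to 0.984), above the 0.8 set in advance, which argues against sex as the whole cause, while 69 of the 327 genes still passed. For the MLKL triple knockout, with no male mouse, it was 0.865 (quartiles 0.751 to 0.997), above 0.8 by less than this spread, a reading changed from exclusion to open after the value was seen; the median absolute log2 fold change went from 0.763 to 0.608. The ratio of SEs with and without the term, taken for each gene, had a median of 1.13, between the bounds set in advance. The median SE itself went from 0.173 to 0.189. A smaller change and a lower precision therefore cannot be told apart for the 132 genes, of which 11 still passed. The direction held in all 327 and 132 genes, and a difference between genotypes stays open in both.

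Chance in the grouping of the libraries was tested with 100 splits per comparison, the real one included. The splits argue against it where 1 of the 100 splits, the real one, gave as many genes. The 11 comparisons were not corrected for their number. The real number and the highest of the other splits were 13 and 1 for the Xbp1 knockout against WT, 181 and 2 for the Casp8 knockout against WT and 3291 and 1130 for the double knockout against WT. They were 1335 and 649 for the double against the Xbp1 knockout and 2842 and 899 for the double against the Casp8 knockout. They were 1182 and 666 for the MLKL triple against the double knockout, 327 and 4 for the TNFR1 triple knockout against WT and 132 and 59 for the MLKL triple knockout against WT. For the TNFR1 triple against the double knockout 2 of 100 splits gave as many (363, highest other 596), and for the TNFR1 against the MLKL triple knockout 2 of 100 (40, highest other 77). These shares lay under the 5 of 100 set in advance. In both, however, another split gave more genes than the real one, so chance is not excluded there. The larger split of the TNFR1 triple against the double knockout exchanged TNFR1 triple knockout replicate 1 with double knockout replicate 3. That of the TNFR1 against the MLKL triple knockout put TNFR1 triple knockout replicates 1, 4 and 5 with MLKL triple knockout replicates 1 and 2. Splits of the 4 groups of the interaction also break up the effects of each deletion, so they test nothing about it (213, highest other 6), and whether chance can be excluded was left open.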

How the results depend on the processing

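Chosen after seeing the data were the settings of males only, females only and no genes near the targeted loci, the sex term, DESeq2 size factors and limma voom for the overlaps, and leaving out libraries for the overlaps and lists. The number of genes that differed stayed within 1.5-fold in each setting for the double knockout against WT. Other comparisons moved further, given here with WT as the second group unless another is named. With no low-count filter, it was 28 for the Xbp1 knockout, 209 for the MLKL triple knockout and 72 for the TNFR1 against the MLKL triple knockout. With sex in the model, it was 8 for the Xbp1 knockout, 101 for the Casp8 knockout, 55 for the interaction, 74 for the TNFR1 triple knockout and 11 for the MLKL triple knockout. In a fit of only the groups compared, it was 225 for the Xbp1 knockout, 435 for the Casp8 knockout, 797 for the double against the Xbp1 knockout, 1570 for the double against the Casp8 knockout and 107 for the interaction. It was 21 for the TNFR1 triple against the double knockout, 490 for the MLKL triple against the double knockout, 306 for the MLKL triple knockout and 19 for the TNFR1 against the MLKL triple knockout. By DESeq2, it was 135 for the Xbp1 knockout, 356 for the Casp8 knockout, 495 for the interaction, 560 for the TNFR1 triple knockout and 291 for the MLKL triple knockout. It was 86 for the TNFR1 against the MLKL triple knockout. By limma voom with quality weights, it was 424 for the Xbp1 knockout, 505 for the Casp8 knockout, 411 for the interaction, 836 for the TNFR1 triple knockout and 350 for the MLKL triple knockout. In males only, it was 2 for the Xbp1 knockout, 24 for the Casp8 knockout, 737 for the double against the Xbp1 knockout, 1298 for the double against the Casp8 knockout and 37 for the interaction. With a stricter low-count filter, it was 122 for the interaction. With the replicate number as a block, it was 73 for the interaction. Without genes near the targeted loci, it was 26 for the TNFR1 against the MLKL triple knockout. For shared calls with the double knockout, the Xbp1 knockout had 110 by DESeq2, 152 in a fit of only the groups compared, 8 with sex in the model and 297 by limma voom with quality weights. The Casp8 knockout had 164 by DESeq2, 177 in a fit of only the groups compared, 48 with sex in the model and 231 by limma voom with quality weights. In a fit of only the groups compared, the genes reversed in the triple knockouts were 19 for TNFR1 and 428 for MLKL. Fits in 1 sex or of only some groups hold fewer samples, and fits without genes near the loci hold fewer genes. Fewer samples do not account for counts that rose in a fit of only the groups compared, such as 225 in place of 13 for the Xbp1 knockout. Replicate pairs spread by 3.25 to 9.27 times a Poisson spread in WT and by 7.41 to 52.4 times in the double knockout. The main fit used 1 dispersion per gene for all groups, and a fit of only the groups compared took it from those groups. Whether this moved the counts, and any other cause, was not tested.

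Leaving out 1 library in turn gave 2 to 14 genes for the Xbp1 knockout, 88 to 188 genes for the Casp8 knockout and 2580 to 3383 genes for the double knockout. It gave 748 to 1681 genes for the double against the Xbp1 knockout, 2002 to 3243 genes for the double against the Casp8 knockout, 41 to 465 genes for the interaction and 63 to 931 genes for the TNFR1 triple against the double knockout. It gave 720 to 1331 genes for the MLKL triple against the double knockout, 77 to 507 genes for the TNFR1 triple knockout, 9 to 131 genes for the MLKL triple knockout and 20 to 54 genes for the TNFR1 against the MLKL triple knockout. For the calls shared with the double knockout it gave 2 to 20 for the Xbp1 and 32 to 153 for the Casp8 knockout. For the reversed genes it gave 53 to 777 for TNFR1 and 562 to 1051 for MLKL. Fits without a library hold fewer samples, and the cause of a change was otherwise not tested.

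The replicate numbers do not pair the samples. Of 75 pairs of libraries with the same number 19 had a correlation of their deviations over 0.1 (range −0.270 to 0.278), and 7 of 30 libraries correlated best with their own number. With the replicate number as a block, 73 genes passed in the interaction in place of 213, and the other counts stayed within 1.5-fold. They were 9 for the Xbp1 knockout, 154 for the Casp8 knockout, 3132 for the double knockout, 1175 for the double against the Xbp1 knockout and 2659 for the double against the Casp8 knockout. Further counts were 289 for the TNFR1 triple against the double knockout, 1066 for the MLKL triple against the double knockout, 290 for the TNFR1 triple knockout, 91 for the MLKL triple knockout and 42 for the TNFR1 against the MLKL triple knockout.

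Some directions turned. None of the genes named here passed before the change of setting, and no turned value passed. Casp8 in the Xbp1 knockout against WT was 0.0671 without the library labelled Xbp1_KO replicate 2, and Casp8 between the triple knockouts −8.53e-04 without TNFR1 triple knockout replicate 1. Xbp1 in the double against the Casp8 knockout was −0.0109 without Casp8 knockout replicate 5 and −0.0584 without double knockout replicate 4, and Xbp1 in the MLKL triple knockout against WT 0.00842 without MLKL triple knockout replicate 1, 0.0688 without WT replicate 1 and 0.0411 without WT replicate 3. The interaction term of Mlkl was 0.0814 with sex in the model, 0.0806 by limma voom, 1.18 in males only and 0.22 without Xbp1 knockout replicate 5. Tnfrsf1a in the MLKL triple knockout against WT was −0.00459 by limma voom and −0.0577 and −0.0325 without MLKL triple knockout replicates 3 and 4. The lists had passed by camera with the preset correlation before the change of setting. In the Casp8 knockout against WT, the median of type I interferon genes was −0.0647 in males only, in place of 0.735 over all mice. Between the triple knockouts, the median of type I interferon genes was 0.48 without the library labelled Xbp1_Casp8_Mlkl_KO replicate 5. That of interferon gamma genes was −0.46 between the triple knockouts without TNFR1 triple knockout replicate 1. Without each library in turn, Casp8 ran over −0.26 to 0.0671 and −8.53e-04 to 0.41 in its comparisons, in the order given here, and Xbp1 over −0.0584 to 0.27 and −0.15 to 0.0688. Mlkl ran over −0.59 to 0.22, Tnfrsf1a over −0.0577 to 0.11, and between the triple knockouts type I interferon genes over −1.79 to 0.48 and interferon gamma genes over −0.46 to 1.09. The cause was not tested.

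Of the named genes that passed, those that also did so in each setting and without each library were 1 of 4 for the Xbp1 knockout, 2 of 24 for the Casp8 knockout, 73 of 82 for the double knockout and 46 of 65 for the double against the Xbp1 knockout. They were 42 of 56 for the double against the Casp8 knockout, 6 of 18 for the interaction, 10 of 43 for the TNFR1 triple against the double knockout and 43 of 66 for the MLKL triple against the double knockout. They were 17 of 36 for the TNFR1 triple knockout, 5 of 26 for the MLKL triple knockout and 9 of 17 for the TNFR1 against the MLKL triple knockout. All 155 calls of lists by camera ended with an estimated correlation. At about 0.232 CPM a read, genes under a few CPM rest on few reads, and small changes were often missed at 5 mice a group.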

Other observations

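Muc2 in the Casp8 knockout stood at 1699 ± 154 CPM (SD, n = 5) and in the groups labelled as lacking Xbp1 at 501 ± 56.9 (Xbp1 knockout), 697 ± 186 (double knockout), 430 ± 189 (TNFR1) and 649 ± 72.2 (MLKL triple knockout). All 20 libraries of these groups lay under the lowest WT library (1597 CPM). In Ak7 the Casp8 knockout libraries held at most 1.73 CPM and the library labelled Xbp1_KO replicate 2 held 1.85, while every other library, double and triple knockouts included, held at least 48.9. Muc2 and Ak7 were looked at by library after their values had been seen.

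Between the sexes over all groups, 16 genes differed by edgeR, 8 higher in males and 8 in females, and 3 of them lie on autosomes. These were higher in males: Mmp7, a matrix protease (log2 fold change 3.82 ± 0.727, adjusted p = 0.0111), Crispld2 (0.47 ± 0.0902, adjusted p = 0.0111) and Tns1 (0.39 ± 0.0771, adjusted p = 0.0186), named after their values were seen. The groups differ in their share of each sex, so values of Mmp7 between groups also carry it.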
